A study of Mus musculus with 7 samples.

How the data were processed

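Small RNA was sequenced from extracellular vesicles, the membrane-bound particles that cells release, isolated from adipose tissue of male C57BL/6J mice. Per the labels, 4 libraries came from mice on a chow diet and 3 from mice on a high-fat diet (HFD), and the diets lasted 12 weeks. Per the labels' protocols, RNA was extracted with Trizol and a sequencing company built the small RNA libraries with Illumina chemistry. The labels do not name the fat depot, and they do not say whether each library came from a separate animal or from pooled mice.

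The deposited values are raw read counts per mature microRNA (miRNA), per the file headers, in a table for each diet and in a combined table of all 7 libraries. The submitters' processing notes name Bowtie as a tool, with no version. The counting program, genome build, miRNA annotation release and filters are not given in the sources used here. The combined table holds 1084 entries, of which 1038 are annotated mature miRNAs and 46 are numbered predictions without a miRNA name, and the predictions held at most 0.0051% of the counts of any library. In the separate Chow table, Chow 2 and Chow 3 have no value for the same 485 entries (439 annotated miRNAs and all 46 predictions), and the combined table holds these as 0. Another 190 entries carry a written 0 in both of these libraries. Apart from the blanks, 0 values differed between the combined and the separate tables. The combined table was used.

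Total counts ranged from 48840 in Chow 3 to 5941955 in HFD 3. A count of 0 allows up to 3 counts, which corresponds to 61.4 CPM (the count scaled to a common library total) in Chow 3, 16.6 CPM in Chow 2 and between 0.505 and 1.64 CPM in the other 5 libraries. Such floors, and the confidence intervals of shares, cover counting error only, because PCR reads without molecular identifiers are not independent molecules.

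Differential abundance was tested in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16 on the deposited counts, with TMM scaling, the filterByExpr filter, diet as the only term and Benjamini-Hochberg adjustment over all tested miRNAs at a threshold of 0.05. Standard errors (SE) of log2 fold changes were derived from the F statistic. Normalised CPM use the TMM-scaled library size as that total. Fixed lists of miRNAs, 20 in all, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, two-sided, for lists with at least 3 tested members, and again with an estimated correlation. The lists covered adipogenic and anti-adipogenic miRNAs, brown and beige fat, miRNAs reported as raised or lowered in obese fat, vesicle cargo named in obesity work, markers of leukocytes, endothelium, stroma and smooth muscle, red blood cells, striated muscle, hepatocytes, neural cells, epithelium and the male reproductive tract, and 5 families or clusters (let-7, miR-17-92, miR-29 with miR-30, Dlk1-Dio3 and Sfmbt2). Composition measures, 7 in all, were compared with an exact two-sided permutation test over all 35 assignments of the libraries, with Benjamini-Hochberg adjustment over the measures, so that 0.0286 was the smallest p possible. Agreement between libraries was described with Spearman correlations across miRNAs and principal components, without a test.

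The tests, the lists, the alternative settings and the rule for naming miRNAs were fixed before the data were examined. The rule took up to 8 miRNAs with the largest fold change in each direction among those past the threshold with a mean of at least 10 CPM and no overlap between groups, the 10 most abundant miRNAs, up to 4 members of each list with the smallest p, and, where fewer than 5 passed in a direction, the 5 with the smallest p in it. The text names a subset of these, and miRNAs outside the rule are identified as chosen after their values were seen. Alternatives were other scalings, other filters, DESeq2 1.42.0, limma-voom with and without sample weights, omission of each library in turn, replicate number as a block, the separate tables, and omission of the 3 most abundant miRNAs or of the predictions. For the lists, fry and the omission of the erythroid list were added, and for the composition a higher detection limit and thinning of the counts to the smallest total. Chosen after the data were seen were the omission of Chow 2 and Chow 3 together, a model term for these libraries, the restriction to entries listed for all 7 libraries, and the counting of near-identical entries once.

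The tests were checked on 20 simulated tables drawn from the means and library sizes of the 7 libraries, each with 200 miRNAs changed by known amounts and a median of 395 miRNAs tested. For the HFD against Chow design, 6.38% of miRNAs changed 2-fold, 47.0% of those changed 4-fold and 99.2% of those changed 16-fold were recovered, and 2.59% of calls were unchanged miRNAs. Without any simulated change, a mean of 0.05 miRNAs and 0.2 lists passed. Each miRNA was drawn independently, whereas the estimated correlation between members of the leukocyte list was 0.63. Chow 2 and Chow 3 were simulated like the other Chow libraries apart from library size, without the shared blank entries of the deposited Chow table. The simulation therefore cannot show how often miRNAs or lists pass by chance in these libraries. All 21 pairs of libraries differed by more than counting error in chi-square tests, so none was treated as a repeat deposit.

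Entries whose counts agreed within 5% formed 13 pairs. Of these, 7 lie on opposite strands of overlapping precursors in the GENCODE M21 annotation (GRCm38), among them miR-142a-3p and miR-142b, and no source states whether counting used the strand, so their reads cannot be told apart. Positions of precursors are given by name from GENCODE M21, which may not be the annotation behind the counts.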

Results

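The miRNA content of extracellular vesicles from adipose tissue was compared between male mice fed chow (4 libraries, Chow 1 to Chow 4) and mice fed a high-fat diet for 12 weeks (3 libraries, HFD 1 to HFD 3). The question set by the design is which vesicle miRNAs differ with diet. The Chow libraries held 2120171, 180694, 48840 and 2294878 miRNA counts, and the HFD libraries held 1969840, 1825488 and 5941955. At least 1 count was found for 654, 386, 265 and 699 miRNAs in Chow 1 to Chow 4 and for 680, 724 and 864 in HFD 1 to HFD 3. The shallowest libraries, Chow 2 and Chow 3, were also those that lacked values for the same 485 entries, and no HFD library had such blanks. No label states that libraries of a diet came from separate animals, so the p-values measure the spread between these libraries, which may be technical.

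**Figure D1:**
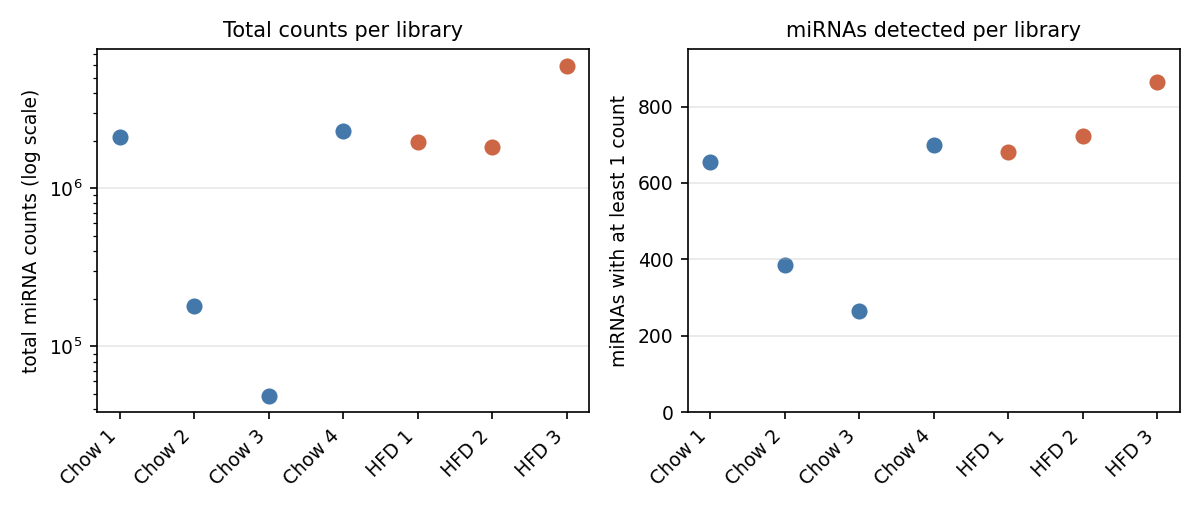
Total miRNA counts (left, log scale) and number of miRNAs with at least 1 count (right) for each library, with Chow in blue and HFD in orange; each point is 1 library. Chow 2 and Chow 3, with 180694 and 48840 counts, lie below the other 5 libraries in both panels.

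The HFD libraries resembled each other more than the Chow libraries did. Spearman correlations of log2 CPM across miRNAs, which are not independent replicates, ranged from 0.924 to 0.965 within HFD, from 0.805 to 0.917 within Chow and from 0.742 to 0.921 between the diets. Pairs that included Chow 2 or Chow 3 had a median of 0.812, and pairs of the other 5 libraries a median of 0.917. The first principal component carried 62.9% of the variance and set Chow 3 (44.6) and Chow 2 (15.4) apart from the remaining libraries, which lay between -16.1 and -7.52.

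A few miRNAs made up most of the vesicle counts. Some shares did not overlap between the diets, but no composition measure passed the adjusted threshold. miR-148a-3p, a miRNA reported to promote fat cell differentiation, was the most abundant in every library and held 49.7% ± 9.31 (SD, n = 4) of the counts in Chow and 23.8% ± 2.71 (SD, n = 3) in HFD. The let-7 family held 6.43% ± 1.28 in Chow and 14.6% ± 1.16 in HFD. The leukocyte list held 3.53% ± 0.994 in Chow and 14.1% ± 1.37 in HFD, most of it miR-21a-5p, which took between 1.71% and 3.74% of the counts in Chow libraries and between 11.1% and 12.5% in HFD libraries. For these 3 shares the libraries of the diets did not overlap, with an exact two-sided permutation p of 0.0286, the smallest that 35 assignments allow, and an adjusted p of 0.0667, above the threshold. The 3 shares are parts of the same total, so a lower miR-148a-3p share by itself raises the others, and they are not separate results. Shares of the counts without miR-148a-3p were not compared. The 10 most abundant miRNAs together held 80.7% ± 3.46 in Chow and 72.4% ± 0.910 in HFD (exact permutation p = 0.0571, adjusted p = 0.1). The erythroid share was 0.325% ± 0.126 in Chow and 0.227% ± 0.112 in HFD (exact permutation p = 0.4). Total counts (exact permutation p = 0.286) and the number of miRNAs detected (501 ± 209 in Chow and 756 ± 96.1 in HFD, exact permutation p = 0.171) did not pass either. With counts thinned to the smallest total of 48840, Chow libraries held between 265 and 304 detected miRNAs and HFD libraries between 311 and 330 (exact permutation p = 0.0571, adjusted p = 0.08). Without Chow 2 and Chow 3, the Chow mean of the miR-148a-3p share was 48.4% and the exact permutation p was 0.1, the smallest that 10 assignments allow. In single libraries the share of miR-148a-3p had exact binomial (Clopper-Pearson) 95% intervals as narrow as 20.99% to 21.06% in HFD 3 and as wide as 57.5% to 58.4% in Chow 3.

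In the main test, the HFD libraries held more miR-223-3p, miR-342-3p, miR-142a and miR-21a-5p and less miR-143-3p, miR-148a-3p and miR-126a-3p than the Chow libraries. The calls depended on single libraries and on the method, as given below. With near-identical entries counted once, regrouping of the libraries did not exclude chance. In edgeR's quasi-likelihood test, 11 of 385 tested miRNAs passed the adjusted threshold, 8 higher and 3 lower in HFD. miR-223-3p, abundant in neutrophils and monocytes, rose 9.22-fold in the edgeR fit. Its means were 14.3 ± 15.04 normalised CPM (SD, n = 4) in Chow and 168 ± 22.4 (SD, n = 3) in HFD. It had 53, 3, 0 and 17 counts in Chow 1 to Chow 4, so its Chow 2 and Chow 3 values did not exceed the floors of those libraries. Its log2 fold change was 3.20 (SE 0.64, edgeR adjusted p = 0.0328), 4.23 without Chow 1 and 2.98 without Chow 2 and Chow 3. miR-342-3p rose from 90.6 ± 67.0 to 620 ± 13.6 normalised CPM (log2 fold change 2.64, SE 0.53, edgeR adjusted p = 0.0328), with 1 count in Chow 3. Both arms of miR-142a, which is characteristic of blood cell lineages, also rose. miR-142a-3p went from 74.8 ± 45.7 to 574 ± 396 normalised CPM (log2 fold change 2.79, SE 0.62), with 1 count in Chow 3. miR-142a-5p went from 623 ± 210 to 2570.4 ± 1256 (log2 fold change 2.03, SE 0.47). The entry miR-142b had the counts of miR-142a-3p and lies on the opposite strand of the same site, so the call belongs to either or both, and 10 calls remained when near-identical entries were counted once.

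miR-21a-5p, a miRNA widely reported to rise in inflamed tissue, increased 3.36-fold, from 31964 ± 16284 to 107307 ± 5320 normalised CPM (log2 fold change 1.75, SE 0.38). let-7f-5p rose 2.48-fold, from 27937 ± 5669 to 69280 ± 5063 normalised CPM (log2 fold change 1.31, SE 0.28). The scarce arm miR-27b-5p rose from 4.01 ± 2.83 to 33.7 ± 4.43 normalised CPM (log2 fold change 2.63, SE 0.54), while its abundant partner miR-27b-3p had a log2 fold change of 0.78 that did not pass (edgeR adjusted p = 0.172).

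The miRNAs that fell were miR-143-3p, miR-148a-3p and miR-126a-3p. miR-143-3p, typical of smooth muscle and stroma and also reported in fat cell differentiation, was 5.97-fold lower in HFD, with 15006 ± 5237 normalised CPM in Chow and 2511 ± 928 in HFD (log2 fold change -2.58, SE 0.43, edgeR adjusted p = 0.0224). miR-126a-3p, a miRNA of blood vessel lining cells, was 3.27-fold lower, with 3073 ± 1302 in Chow and 939 ± 21.2 in HFD (log2 fold change -1.71, SE 0.41, edgeR adjusted p = 0.0491). Its scarce partner arm miR-126a-5p had a log2 fold change of -0.36 that did not pass (edgeR adjusted p = 0.808), and -0.92 without Chow 2 and Chow 3. miR-148a-3p had a log2 fold change of -1.39 (SE 0.30, edgeR adjusted p = 0.0328). The next lowest p-values in this direction belonged to miR-30a-3p, with a log2 fold change of -1.92 (edgeR adjusted p = 0.0558), and miR-708-5p, with -1.96 (edgeR adjusted p = 0.0642), neither of which passed.

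Several of these miRNAs are encoded within host genes in GENCODE M21 (GRCm38). The miR-126a precursor lies on chromosome 2 at 26591357 to 26591429 within Egfl7, an endothelial gene. The miR-342 precursor lies on chromosome 12 at 108658620 to 108658718 within Evl, and that of miR-21a on chromosome 11 at 86584067 to 86584158 within Vmp1. The miR-142a precursor lies on chromosome 11 at 87756864 to 87756927 within the noncoding gene Mir142hg, and that of miR-223 on chromosome X at 96242817 to 96242926. Neither the miR-148a precursor, on chromosome 6 at 51269812 to 51269910, nor that of miR-143, on chromosome 18 at 61649196 to 61649258, lies within another annotated gene.

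**Figure D2:**
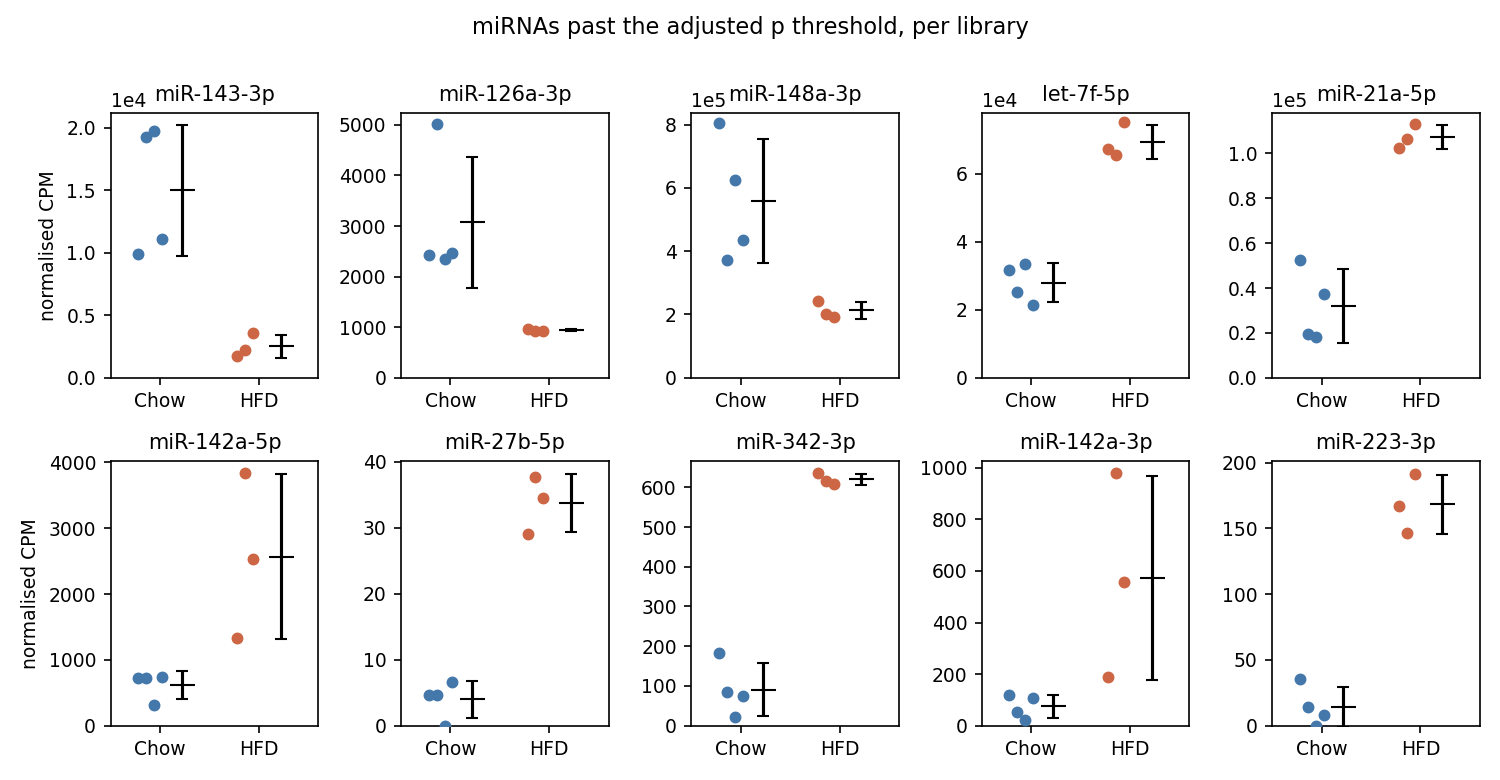
Normalised CPM per library (vertical axes, linear and starting at 0) in Chow (blue, 4 libraries) and HFD (orange, 3 libraries) for the miRNAs past the edgeR threshold, with miR-142b, which shares the counts of miR-142a-3p, left out; each point is 1 library, and bars give the mean ± SD beside the points. In each panel the HFD libraries lie on one side of the Chow libraries.

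At an unadjusted p under 0.05 there were 93 miRNAs, where 19 would be expected by chance on average. For 86 of the 385 the libraries of the diets did not overlap, where chance gives 5.71% on average. Because miRNAs vary together, a single assignment of the libraries can exceed these averages without an effect of diet. Neither count was made for other assignments, so they cannot decide whether diet had a broad effect. The number of calls depended on single libraries, with 32 calls without Chow 1, 4 without Chow 2, 6 without Chow 3 and 1 without Chow 4. There were 11 without HFD 1 (8 of them among the main calls), 0 without HFD 2 and 1 without HFD 3. Without HFD 2, edgeR gave 57 at an unadjusted p under 0.05, and DESeq2 gave 13 past the threshold and limma-voom 0. The number also depended on the method, with 47 calls in DESeq2 (31 higher, 16 lower) and 39 with library size as the only scaling (36 higher, 3 lower). Without Chow 2 and Chow 3, all 11 miRNAs kept their direction and had an unadjusted p under 0.05, but 0 of 403 passed in edgeR (95 at an unadjusted p under 0.05, smallest adjusted p 0.0570), whereas 40 passed in DESeq2 and 1 in limma-voom.

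Among the other abundant miRNAs, none passed the test. miR-10b-5p averaged 74649 ± 39518 normalised CPM in Chow and 69232 ± 15527 in HFD, and miR-10a-5p 54812 ± 29873 and 53553 ± 11487. miR-99a-5p averaged 67671 ± 12641 and 60031 ± 11720. The sign of these 3 fold changes, which lay between -0.17 and -0.03, turned positive under library size scaling. miR-30a-5p averaged 31030 ± 10063 in Chow and 18948 ± 5766 in HFD, miR-30d-5p 16856 ± 3556 and 20821 ± 3688, and miR-26a-5p 10619 ± 3938 and 18170 ± 4267. let-7g-5p averaged 9941 ± 3691 and 18070 ± 1556, with an edgeR adjusted p of 0.163.

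With the preset correlation, miRNAs reported in earlier work as raised in obese fat were higher in HFD vesicles as a group (camera adjusted p = 0.00194) and those reported as lowered were lower (camera adjusted p = 0.00240). With an estimated correlation the adjusted p was 0.770 and 0.361, so neither call held. Of 13 tested members of the raised list, 5 rose (miR-223-3p, miR-142a-3p, miR-342-3p, miR-142a-5p and miR-21a-5p) and none fell in edgeR, 12 had a positive fold change, and the median log2 fold change was 1.32. Adjusted over the list alone, 8 rose and 1 fell. Of 13 tested members of the lowered list, 3 fell (miR-143-3p, miR-126a-3p and miR-148a-3p) and none rose, with the same counts adjusted over the list alone, and the median was -0.61.

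Leukocyte markers were higher in HFD as a group with the preset correlation (camera adjusted p = 0.00691), a call that did not hold with an estimated correlation (adjusted p = 0.770). Of 16 tested members, 5 rose and none fell, and the median log2 fold change was 1.30. These were the same 5 miRNAs as in the raised list, with which the leukocyte list shares 8 tested members. Adjusted over the list alone, 8 rose and 1 fell. The one that fell, chosen for naming after its values were seen, was miR-147-3p, with a log2 fold change of -1.44 and an adjusted p of 0.136 over all miRNAs in edgeR.

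Markers of testis and epididymis, organs that adjoin a white fat depot of male mice, formed the list with the smallest p in camera with the preset correlation. With an estimated correlation and in fry, the lowered list had the smallest unadjusted p (0.0181 in camera and 0.00387 in fry). Of 18 tested members of the testis and epididymis list, none rose or fell over all miRNAs. Adjusted over the list alone, 9 rose and none fell, 17 had a positive fold change, and the median was 1.65. The members with the smallest p were miR-470-5p (log2 fold change 2.42, SE 0.68), miR-883a-3p (2.80, SE 0.81), miR-743a-3p (1.98, SE 0.63) and miR-741-3p (2.29, SE 0.74). Without HFD 1, miR-470-5p had 1.83 and miR-883a-3p 2.05, and without Chow 1, miR-883a-3p had 3.76 and miR-741-3p 3.15. miR-883a-3p is 1 of 19 tested miRNAs with no value in Chow 2 and Chow 3, held as 0. It had 12 counts in Chow 1 and 6 in Chow 4, so without Chow 1 its Chow level rests on those 6 counts. Levels of these members were low, at 10.7 ± 7.71 normalised CPM in Chow and 43.9 ± 32.2 in HFD for miR-470-5p, near or below the floors of Chow 2 and Chow 3. The adjusted p in camera was 0.000711, and the adjusted p was 0.770 with an estimated correlation. For none of the 4 lists past the threshold did the preset call hold with an estimated correlation, and regrouping of the libraries gave p-values as small for each of them in at least 2 of 35 assignments, the diet split included.

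**Figure D3:**
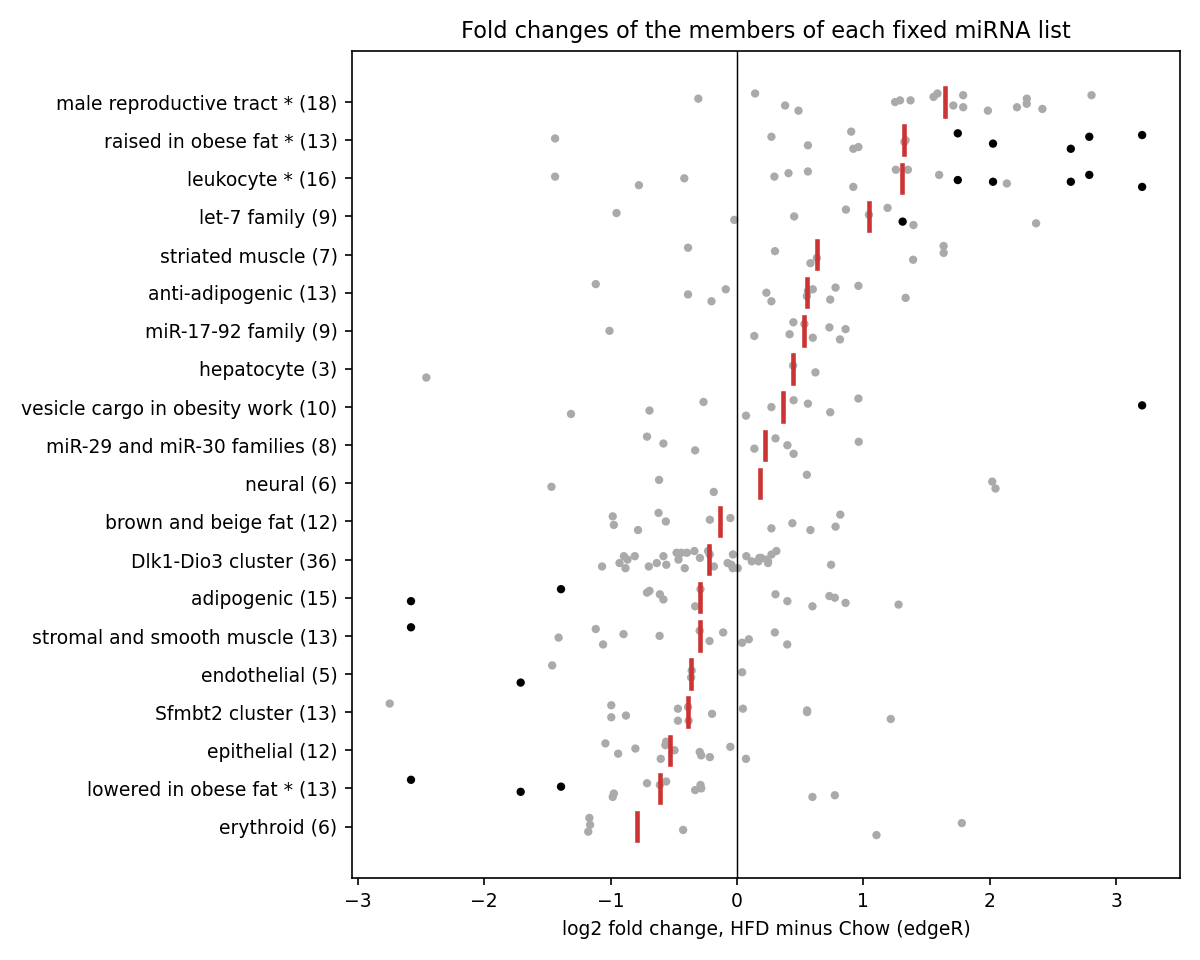
Log2 fold change of HFD minus Chow (edgeR, horizontal axis) for each tested member of the 20 fixed lists, with the number of tested members in parentheses; points are miRNAs, black where past the adjusted threshold, red bars are list medians, and asterisks mark the 4 lists past the camera threshold with the preset correlation. Medians ranged from -0.79 for the erythroid list to 1.65 for the male reproductive tract list.

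The other 16 lists did not pass. In the let-7 family, 1 of 9 tested members rose (let-7f-5p), and adjusted over the list alone 6 rose and 1 fell (median 1.04, camera adjusted p = 0.105). Its members miR-98-5p, let-7a-5p and let-7d-5p had log2 fold changes of 2.37, 1.40 and 1.19 that did not pass over all miRNAs. Among 15 adipogenic miRNAs, of which 8 are shared with the lowered list, 2 fell, miR-143-3p and miR-148a-3p, and none rose, with the same counts adjusted over the list alone (median -0.29, camera adjusted p = 0.314). None of 13 anti-adipogenic members passed (median 0.55, camera adjusted p = 0.279), with log2 fold changes of 1.33 for miR-221-3p and 0.96 for miR-222-3p. None of 12 members of the brown and beige fat list passed (median -0.13, camera adjusted p = 0.526), with values of -0.98 for miR-365-3p and -0.78 for miR-455-5p. In the vesicle cargo list, 1 of 10 rose, miR-223-3p (median 0.36, camera adjusted p = 0.526).

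Among cell type markers, 1 of 5 endothelial members fell over all miRNAs, miR-126a-3p, and 2 fell when adjusted over the list alone (median -0.36, camera adjusted p = 0.279). Of 13 stromal and smooth muscle members, 1 fell, miR-143-3p (median -0.29, camera adjusted p = 0.0837), and values of -1.12 for miR-145a-5p and -1.06 for miR-100-5p did not pass. No epithelial member passed, although 11 of 12 had a negative fold change (median -0.53, camera adjusted p = 0.182), with -0.94 for miR-183-5p and -0.56 for miR-200a-3p. No member passed in the erythroid (6 tested, median -0.79, camera adjusted p = 0.279) or striated muscle (7 tested, median 0.63, camera adjusted p = 0.279) lists, where miR-486a-3p had -1.17 and miR-1a-3p 1.63 (0.50 without HFD 1 and 2.85 without Chow 4). In the neural list (6 tested, median 0.18, camera adjusted p = 0.526), miR-9-5p and miR-9-3p had log2 fold changes of 2.04 (1.40 without HFD 2 and 2.65 without HFD 1) and 2.02 (3.34 without Chow 2). In the hepatocyte list (3 tested, median 0.44, camera adjusted p = 0.526), miR-122-5p had -2.46. The value was -1.43 without Chow 3, where miR-122-5p stood at 1850 CPM on 84 counts against 257 to 428 CPM in the other Chow libraries, and -1.23 without Chow 2 and Chow 3. Adjusted over the list alone, 1 member rose in the neural list and 1 fell in the hepatocyte list. The miR-17-92 family (9 tested, median 0.53, camera adjusted p = 0.279), the miR-29 and miR-30 families (8 tested, median 0.22, camera adjusted p = 0.960), the Dlk1-Dio3 cluster (36 tested, median -0.22, camera adjusted p = 0.480) and the Sfmbt2 cluster (13 tested, median -0.39, camera adjusted p = 0.526) had no member past the threshold. Where no other count is given, the count adjusted over the list alone equalled that over all miRNAs. In 8 of the 16 lists (brown and beige fat, endothelial, erythroid, hepatocyte, epithelial, miR-29 and miR-30, Dlk1-Dio3 and Sfmbt2) the direction of the camera test was down while the edgeR median printed here, or the median or mean on the log2 CPM scale that camera uses, was positive. Without Chow 2 and Chow 3, 9 lists passed with the preset correlation, the 4 above and the endothelial, stromal, epithelial, let-7 and Dlk1-Dio3 lists, and none with an estimated correlation (smallest adjusted p 0.427).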

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

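Within Chow (4 libraries; single values of the 3 HFD libraries were not tested in this way), 6 of 64 sets of values had a library farther from the others than Dixon's ratio for 4 values allows; chance marks about 1 in 20. All 6 lay in Chow 2 or Chow 3. miR-126a-3p stood at 5025 normalised CPM in Chow 2 and between 2357 and 2473 in the other Chow libraries, and without Chow 2 and Chow 3 its log2 fold change was -1.39. miR-142a-5p stood at 308 normalised CPM in Chow 3 and between 717 and 747 elsewhere in Chow. let-7a-5p stood at 1499.5 normalised CPM in Chow 2 against 5287 to 6168. miR-193b-3p stood at 4.70 in Chow 2, below that library's floor of 16.6 CPM, against 22.03 to 29.6. miR-27b-5p had 0 counts in Chow 3 against 4.65 to 6.68 normalised CPM, and miR-144-5p 0 against 8.11 to 9.40, both under the 61.4 CPM that a count of 0 allows there.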

How the results depend on the processing

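Across 23 alternatives, all 250 values of the 11 called miRNAs kept their direction and 172 stayed past the threshold. Of 1053 values of 46 other miRNAs examined, 77 passed and 19 turned sign. The main count of 11 became 18 with DESeq2 size factors in edgeR, 39 with library size only, 62 without a filter, 47 in DESeq2 and 19 in limma-voom with sample weights; other scalings, filters, tests and tables gave 10 to 16. Leaving out 1 library gave 0 (without HFD 2) to 32 (without Chow 1). With both shallow libraries left out, or with a term for them, choices made after the data were seen, edgeR gave 0 (95 and 76 at an unadjusted p under 0.05); fewer libraries or degrees of freedom are part of that construction. Relative to TMM, the median log2 fold change of all miRNAs moved by 0.11 with DESeq2 size factors and 0.33 with library size only. The replicate number as a block, for libraries 1 to 3 of each diet, gave 22 calls (9 of the 11 kept). Deviations of same-numbered libraries correlated at 0.07, -0.16 and 0.04. These values give no sign of a pairing but, with Chow 2 and Chow 3 so shallow, cannot exclude one. Of all 20 lists, 4 passed in the main test, 0 with an estimated correlation and 0 in fry (1 and 3 at an unadjusted p under 0.05), with unchanged medians for the 4 on the log2 CPM scale (1.66 raised, -0.58 lowered, 1.82 leukocyte, 1.96 male reproductive tract). With the preset correlation, 9 of the 20 passed without Chow 2 and Chow 3 and 7 with a term for them. Without these libraries none passed with an estimated correlation (smallest camera adjusted p 0.427), which was not run with the term. The values that turned sign belonged to miRNAs near 0: mmu-miR-10b-5p (0.20 with library size only, 0.26 without a filter, 0.31 in the block, and -0.34 to 0.23 over omissions of 1 library), mmu-miR-10a-5p (0.0648 with DESeq2 size factors, 0.28 with library size only, 0.33 without a filter, 0.0648 in DESeq2, 0.0662 without the 3 most abundant miRNAs, 0.40 in the block, and -0.27 to 0.31 over omissions) and mmu-miR-99a-5p (0.0432 with library size only, 0.13 without a filter, and -0.28 to 0.0312 over omissions). The cause of these changes was not tested. Depth limits Chow 2 and Chow 3: scarce miRNAs there lie under their floors, and 2-fold changes were rarely recovered in simulation (6.38%).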

Other observations

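The tests on leukocyte, testis-associated and miR-182-5p values below were chosen after these patterns were seen, while the counts over regrouped libraries, except where stated, were planned before their results were seen, and the conditions for 4 of the former, those on shallow depth (in both lists), on carry-over and on 1 outside source, were changed after their results were known. Single libraries differed in some miRNAs of other organs in a pattern that crossed the diets, whereas miR-202-5p and miR-9-3p ran more with diet. miR-215-5p, a miRNA of gut and kidney chosen here after its values were seen, stood at 17837 normalised CPM in Chow 4, 13294 in HFD 1 and 10363 in HFD 2, but at 901, 9.40 and 0 in Chow 1 to Chow 3 and 957 in HFD 3. The muscle miRNA miR-1a-3p followed the same libraries, with 1291 in Chow 4, 3323 in HFD 1 and 1191 in HFD 2, and between 98.7 and 374 in the others. When Chow 4, HFD 1 and HFD 2 were set against the other libraries as 1 of 35 possible groupings, 10 miRNAs passed, all of them members of the miR-215, miR-194, miR-192, miR-1, miR-133 or miR-206 families. miR-202-5p, a gonadal miRNA also chosen after its values were seen, stood at 238, 67.5 and 15.9 normalised CPM in HFD 1 to HFD 3 and at 1.33, 4.70, 44.1 and 0.954 in Chow 1 to Chow 4. The diets overlapped only through Chow 3, whose value rests on 2 counts and lies under its floor of 61.4 CPM. The log2 fold change of miR-202-5p was 5.32 (edgeR adjusted p = 0.0510, which did not pass) and 6.51 without Chow 2 and Chow 3. It passed in 6 of 23 alternatives. miR-9-3p stood between 587 and 772 normalised CPM in HFD, at 494 in Chow 2 and between 22.03 and 102 in the other Chow libraries, so the diets did not overlap. Without Chow 2 and Chow 3 its log2 fold change was 3.14 (edgeR adjusted p = 0.0570, which did not pass).

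Regrouping of the 7 libraries into 4 and 3 bears on what the diet split shows. The diet split gave 11 calls and the highest of the others gave 10 (the grouping of Chow 4, HFD 1 and HFD 2 above, and Chow 2, Chow 3 and Chow 4 against the rest), so 1 of 35 groupings reached the real count. With near-identical entries counted once, a test added later, the diet split gave 10 calls and so did Chow 2, Chow 3 and Chow 4 against the rest, so 2 of 35 groupings reached the real count and chance was not excluded. For the number of lists chance was not excluded, since 9 of 35 groupings gave at least the 4 lists of the diet split and the highest other gave 5 (Chow 1, Chow 2 and Chow 3 against the rest). Nor was it excluded for any single list, with camera p-values as small, the diet split included, in 2 groupings for the raised list, 2 for the lowered list, 5 for the leukocyte list and 8 for the male reproductive tract list.

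The higher leukocyte miRNAs in HFD were weighed against technical explanations. Without Chow 2 and Chow 3 the leukocyte median still lay 1.31 above that of the other miRNAs (limma's camera adjusted p = 0.00329 with the preset correlation, and 0.542 with an estimated correlation, which did not pass with all 7 libraries either). The level of the list relative to the other miRNAs (log2) was -0.78 and -0.96 in Chow 1 and Chow 4 and -0.18, 0.50 and 0.45 in HFD 1 to HFD 3, a gap of 0.60 that exceeded the larger SD within a diet (0.38), which argues against the shallow depth and separate handling of Chow 2 and Chow 3 as the whole cause. A smaller share of fat cell RNA would raise every other cell type alike. Without Chow 2 and Chow 3, the leukocyte median lay 1.98 above that of 18 endothelial and stromal members (permutation over miRNAs taken as independent, p = 1e-04). The endothelial and stromal medians were -0.93 and -0.62 on the log2 CPM scale. This would argue against that explanation as the whole cause only if these members came mainly from cells other than fat cells, which no value here shows. The p itself decides nothing, because members vary together (estimated correlation 0.63 in the leukocyte list over all 7 libraries). The set also holds miR-143-3p, reported in fat cell differentiation, and the near-identical entries miR-126a-5p and miR-126b-3p. Most of its endothelial members come from the overlapping precursors of miR-126a and miR-126b. A chance difference between these libraries and a smaller share of fat cell RNA stay open. So does an effect of diet, which is untested because no value here shows which cells released the vesicles.

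The higher testis-associated miRNAs in HFD may reflect material from another organ or from the depot itself. Without Chow 2 and Chow 3 the list median still lay 1.48 above the other miRNAs (limma's camera adjusted p = 0.00267 with the preset correlation, and 0.572 with an estimated correlation). The level of the list was -0.32 and -1.12 in Chow 1 and Chow 4 and 1.503, 0.49 and -0.55 in HFD 1 to HFD 3. HFD 3 thus lay below Chow 1, and the excess in this level did not exceed the spread between these deeper libraries. With the library total as the only scaling, 12 of the 13 X-linked members were higher in all 3 HFD libraries than in Chow 1 and Chow 4. The measures differ in scaling and in members and give different answers for HFD 3. They therefore cannot decide against the shallow depth of Chow 2 and Chow 3, which stays open. Carry-over of whole testis or epididymis, which should raise autosomal members too, also stays open: the 13 X-linked members had a median log2 fold change of 1.54 and the 5 autosomal ones 0.25, a difference of 1.29 (permutation over miRNAs, p = 0.00335), but miR-449a-5p, the autosomal member with the lowest level in Chow 1 and Chow 4 (4.14 CPM), had 1.13, within the X-linked range of 0.91 to 2.56, and miR-202-5p on chromosome 7 was highest in HFD 1. Whether 1 source reached the HFD libraries in different amounts stays open, since the X-linked members were between 2.77 and 6.21 times higher in HFD 1 than in HFD 3 (median 4.79), which exceeds counting error (chi-square p = 8.86e-15), a bound first taken as decisive against it and then, after the result was seen, judged too strict, since no technical replicates show the spread between libraries. An effect of diet on these miRNAs stays open and untested.

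miR-182-5p had 0 counts in Chow 2 and Chow 3 but 4808 and 3740 in Chow 1 and Chow 4, and 1188, 3086 and 10794 in HFD. Too few reads is argued against, because 349.8 counts would be expected in Chow 2 at the share of Chow 1 and Chow 4, and the neighbouring miR-183-5p had 292 counts there. A separate processing run with its own list of miRNAs is a candidate explanation, since 485 entries are blank in both libraries while 190 others carry a written 0. That comparison covered the entries as a whole. It did not ask whether miR-182-5p itself is blank or a written 0, so it cannot decide for this miRNA. Such a run would hold Chow libraries alone, so for miRNAs it affects the run and the diet cannot be told apart in Chow 2 and Chow 3. Any biological explanation was not tested.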
